A study of Danio rerio with 12 samples.

How the data were processed

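Whole zebrafish embryos were profiled at the 10 somite and 18 somite stages, during segmentation, after injection at the 1 to 2 cell stage with a pair of morpholinos against pbx2 and pbx4 or with a control morpholino that the labels describe as a pbx2 mutant. Morpholinos are antisense oligomers that block translation or splicing of their target. Pbx proteins are TALE homeodomain transcription factors that bind DNA together with Hox and other factors. There were 4 groups of 3 arrays, 12 arrays in all. Per the labels' protocols, RNA was extracted with Trizol and cleaned on Qiagen columns, and biotinylated cRNA made from 6 µg of total RNA was hybridised to Affymetrix zebrafish arrays. The labels number the replicates within each group and do not say that they came from separate clutches or injections, so p-values measure the spread between these samples, which may be technical.

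The deposited values are log2 expression values per probe set, 15617 rows over 12 columns. The submitters' processing notes name RMA and the affy package, with no version, and RMA gives log2 values. Which arrays were normalized together is not given in the sources used here. The medians over probe sets were 7.295, 7.297 and 7.289 on the control arrays at 10 somites, 7.313, 7.289 and 7.292 on the morphant arrays at 10 somites, 6.534, 6.518 and 6.529 on the control arrays at 18 somites and 6.5525, 6.5285 and 6.569 on the morphant arrays at 18 somites, each in the order of the replicate numbers. Arrays of a stage therefore shared a scale, while the stages stood apart by most of a log2 unit. A constant offset cancels within a stage and in the difference between the stages' effects, but not in comparisons of one stage with the other. The quartiles did not shift equally. On the control arrays numbered 1 the lower quartile was 5.60 at 10 somites and 4.85 at 18 somites, and the upper 8.87 and 8.02. The difference between the stages' effects can depend on that. No background or detection value was used here, so no signal was called absent, and the number of arrays limits the precision. The tag range is given by 8 control probe sets for tag sequences that embryos do not carry. Background there can make fold changes smaller or hide a fall. Falls were still called from control signals in that range, such as that of bhlhe22 at 10 somites (5.78 to 4.67, adjusted p = 0.000614). Arrays of 1 group correlated with each other between 0.995 and 0.998 over probe sets, none were identical, and the median SD of a probe set over the 3 arrays of a group was 0.0922 and 0.08 at 10 somites and 0.088 and 0.1 at 18 somites in control and morphant arrays.

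The 115 AFFX control probe sets were left out and 15502 probe sets were tested. The platform annotation paired 10795 of these with 1 gene symbol, 135 with several and 4572 with none, which are unnamed here. Gene IDs of 10711 probe sets matched the table of RefSeq genes of assembly GRCz12tu, used for names only, and 1 symbol was updated. The named probe sets cover 8793 genes, of which 1539 have more than 1 probe set. For tests of gene lists, a gene was represented by the probe set with the highest mean over all arrays.

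A linear model with 1 mean per group was fitted to each probe set with lmFit and eBayes of limma 3.58.1 in R 4.3.3, over all 12 arrays, with 8 residual and 6.06 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 15502 probe sets, and a probe set was called at an adjusted p under 0.05, the false discovery rate the series text gives. The contrasts were the pbx effect at each stage (morphant minus control), the mean of both effects, the difference between them (18 somites minus 10 somites) and the change from 10 to 18 somites in control and in morphant embryos. Values after ± are standard errors of the model unless marked SD. On simulated values with the spread of the real arrays, the pbx effect at 10 somites was called for 91 of 100 probe sets changed by 0.5 and for 100 of 100 changed by 1 on the log2 scale, with 10 false calls among the unchanged ones of 15502. The simulated spread was independent between arrays and left out the deviations that same-numbered arrays share, so real performance may differ.

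The choices of groups, comparisons, gene lists, the rule for named genes and the alternatives were made before the data were examined, except for the replicate block shared by both stages, leaving out the 4 arrays numbered 1, the grouping of Hox genes, the comparison with tag control probe sets and the tests of explanations said to have been chosen after the result was seen. The 26 lists were fast muscle, slow muscle, shared muscle structure, myogenic regulators, TALE homeobox, Hox genes, hindbrain segmentation, eye and midbrain, heart, endoderm and pancreas, blood, vessel, somite segmentation, notochord, neural crest, neurons, neural progenitors, epidermis and hatching gland, yolk layer and plasma proteins, pronephros, p53 and morpholino response, cell cycle, Fgf signalling, Hedgehog signalling, retinoic acid signalling and ribosomal proteins. Some genes stand in more than 1 list. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists of a contrast. The count of called members is given over all probe sets tested and adjusted over the list alone.

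The rule for named genes took probe sets paired with 1 symbol. For each stage it took pbx2 and pbx4, a fixed panel (myod1, myf5, myog, mylpfa, smyhc1, egr2b, hoxb1a, hoxa2b), the 8 lowest and 8 highest log2 fold changes among called genes whose 3 morphant arrays all lay on one side of the 3 control arrays, which chance gives for 10% of genes, and up to 3 called members of each list with the smallest p. For the averaged effect, the difference between stages and the stage effect in controls it took the 5 lowest and 5 highest among the called genes. Other genes named were chosen after their values were seen.

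Replicate numbers are shared by the groups, so it was checked whether they pair the arrays. The deviations of same-numbered control and morphant arrays from their group means correlated between 0.214 and 0.548 over probe sets in all 6 pairs of a stage, against a median of -0.176 for arrays of different number. Deviations from a group mean cancel within the group, so positive values for same-numbered arrays force negative ones elsewhere. That median is therefore no separate baseline. Arrays of different number ranged up to 0.231. The numbers were taken to pair the arrays because each same-numbered correlation was over 0.1, a pairing that comes from the values and not from a statement in the labels; same-numbered arrays also went together across the stages, between 0.18 and 0.485 in 12 pairs. A fit with the replicate number within a stage as a block was the alternative, and its value stands beside a result where it changes a call or moves a count by over 1.5 times.

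Alternatives besides the block were a fit on the arrays compared alone, the 60% of probe sets with the highest mean, an intensity trend in the variance prior, array weights, median centring, quantile normalization of the deposited values, an adjusted p under 0.01, a minimum of 1.5-fold, 1 probe set per gene, leaving out probe sets marked as cross-hybridizing, and leaving out each array. Lists were also tested with an estimated correlation and with the mean of a gene's probe sets, and with fry, which asks whether the members changed at all and not whether they differ from other genes, so its p-values answer another question. Where a range of adjusted p over alternatives is given, it holds the fry values too. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.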

Results

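RNA levels of whole zebrafish embryos were compared between control and pbx2;pbx4 morphants at 10 and 18 somites, with 3 arrays in each of 4 groups. The comparison within a stage asks which transcripts depend on Pbx function during segmentation, when hindbrain, somite muscle and heart form. Values are log2 signals per probe set, and a fold change of 1 on this scale is a doubling.

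The transcripts of both targeted genes were higher in the morphants. The pbx2 probe set read 8.40, 8.47 and 8.76 on the control arrays and 10.30, 10.33 and 10.24 on the morphant arrays at 10 somites, and 7.997, 8.20 and 8.23 against 9.88, 9.92 and 9.52 at 18 somites. The effect was 1.75 ± 0.11 at 10 somites (n = 3 per group, adjusted p = 7.05e-07) and 1.63 ± 0.11 at 18 somites (adjusted p = 1.41e-06). The pbx4 probe set read 11.05, 11.28 and 11.17 in controls and 11.60, 11.61 and 11.63 in morphants at 10 somites, a rise of 0.45 ± 0.09 (adjusted p = 0.00606). At 18 somites it read 10.13, 10.24 and 10.22 against 10.64, 10.65 and 10.34, a rise of 0.34 ± 0.09 (adjusted p = 0.0192). The pbx4 call at 18 somites was lost without the control array numbered 1 (adjusted p = 0.0755) and without the morphant array numbered 1 (0.073) or 2 (0.0757). A morpholino need not lower its target's transcript, so these values do not check the knockdown.

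**Figure D1:**
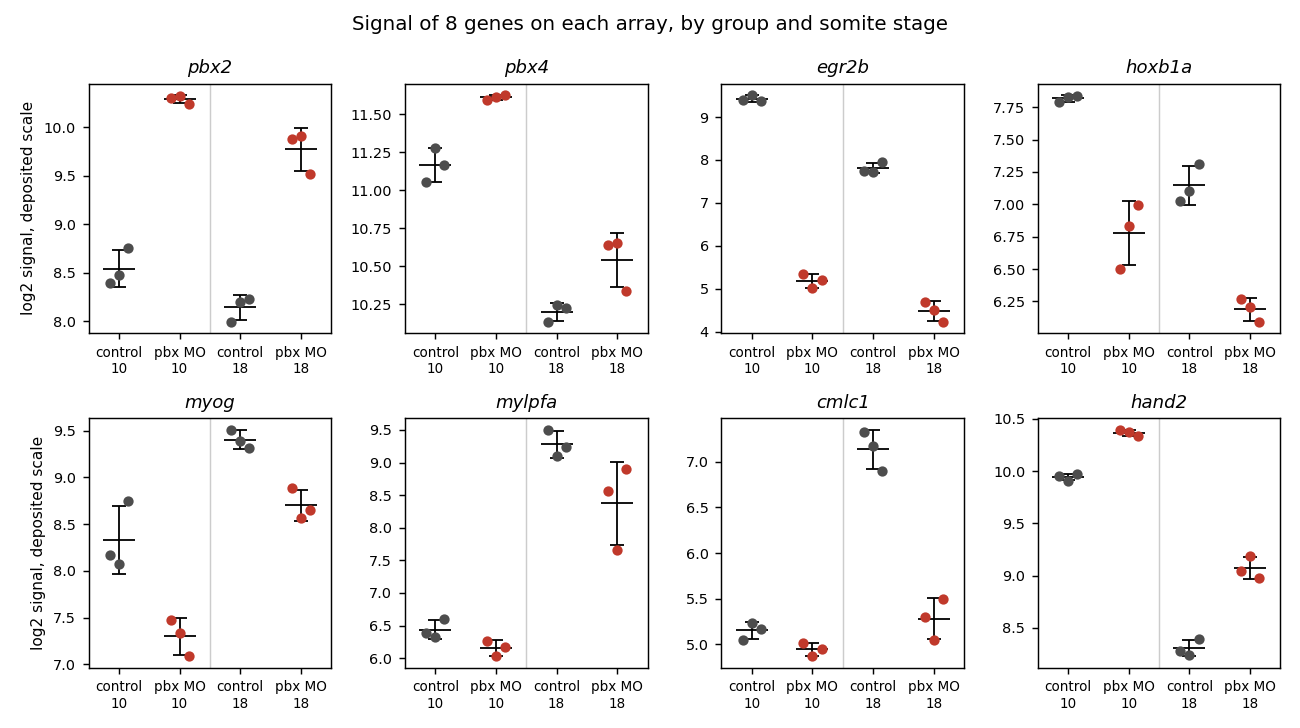
Log2 signal of 8 genes (vertical axis, deposited scale, a separate range per gene) on each array of the 4 groups (horizontal axis); points are arrays, bars the mean and SD of 3 arrays, and the vertical line parts the stages, which do not share a scale. The egr2b signal was 9.43 in controls and 5.18 in morphants at 10 somites, and cmlc1 parted the groups at 18 somites (7.14 against 5.28) more than at 10 somites (5.15 against 4.94, both within the range of control probe sets for tag sequences that embryos do not carry).

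At 10 somites the lowest relative signal in morphants was that of egr2b, the zinc finger factor of rhombomeres 3 and 5, at -4.25 ± 0.11 (control 9.43 ± 0.07, morphant 5.18 ± 0.17, SD, n = 3; adjusted p = 2.47e-11). That morphant signal lay within the range of 8 control probe sets for tag sequences that embryos do not carry (4.26 to 6.04). Background therefore limits the size of the fold change. Other hindbrain genes fell with it: hoxa3a at -1.05 ± 0.07, hoxb1a, the Hox gene of rhombomere 4, at -1.04 ± 0.11, hoxa2b at -0.97 ± 0.09 and cyp26b1, whose enzyme degrades retinoic acid, at -1.33 ± 0.08. The leukocyte actin-bundling gene lcp1 fell by 2.67 ± 0.18, and myog, a transcription factor of muscle differentiation, fell by 1.03 ± 0.15 (adjusted p = 0.000926). The stress response factor atf4a rose by 1.38 ± 0.10, and the mesendoderm genes sox32 and mixl1 rose by 0.91 ± 0.11 and 0.90 ± 0.09. The control signals of sox32 (5.77) and mixl1 (6.08) lay within the tag range on control arrays (4.18 to 6.13), so background limits these sizes too. In all, 1267 of 15502 probe sets were called, 670 higher and 597 lower in morphants, or 620 higher and 621 lower after median centring of each array. Of the 1267, 34 changed at least 2-fold, 9 of them higher and 25 lower.

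The other genes with the lowest fold changes at 10 somites were pnhd at -1.94 ± 0.17, angptl7 at -1.39 ± 0.11, mthfd1b at -1.34 ± 0.07, ambp, a precursor of a plasma protease inhibitor, at -1.18 ± 0.10, and si:dkey-117n7.5 at -1.17 ± 0.10. The highest, besides those above, were the monocarboxylate transporter gene slc16a3b at 1.66 ± 0.21, the protocadherin gene pcdh1b at 2.14-fold, si:ch211-147a11.3 at 0.93 ± 0.11 and rab1bb, a small GTPase of the secretory route, at 0.90 ± 0.11. Each had an adjusted p of 0.000341 or less. The control signals of slc16a3b (5.71), pcdh1b (5.86) and rab1bb (5.14) and the morphant signals of rab1bb (6.03) and si:dkey-117n7.5 (5.16) lay within the tag range, so background limits their sizes and ranks. The probe sets passed over for lack of a symbol numbered 5 among the lowest and 5 among the highest. Of the fixed panel, myod1 (0.21 ± 0.08, adjusted p = 0.145), myf5 (-0.24 ± 0.11, adjusted p = 0.224), mylpfa (-0.28 ± 0.22, adjusted p = 0.512) and smyhc1 (0.14 ± 0.07, adjusted p = 0.247) were not called at this stage. With array weights myod1 was called (adjusted p = 0.0362). With the replicate block 2040 probe sets were called at 10 somites, 1079 higher and 961 lower. Without the control array numbered 1 or 2 the count was 773 or 675, without the morphant array numbered 2 or 3 it was 719 or 643, and without the 4 arrays numbered 1 it was 333.

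Of the 9 lists lower at 10 somites, 4 hold genes of the nervous system. Of 28 measured hindbrain segmentation genes 15 fell and 1 rose, irx1b, named after its value was seen (19 and 1 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.29e-13, and 0.0281 with an estimated correlation). Of 27 neuronal genes 6 fell and none rose (8 fell adjusted over the list alone; median -0.12, and -0.22 among the 60% of probe sets with the highest mean, camera adjusted p = 4.89e-05, and 0.0281 with an estimated correlation). The proneural factors neurog1, ascl1a and ascl1b were at -0.73 ± 0.08, -0.72 ± 0.10 and -0.69 ± 0.08. Of 26 eye and midbrain genes 9 fell and 1 rose (9 and 2 adjusted over the list alone; median -0.12, camera adjusted p = 0.00093, and adjusted p = 0.239 with an estimated correlation). The retinal homeobox genes rx1 and rx2 were at -1.01 ± 0.09 and -0.94 ± 0.11 and pax6a at -0.63 ± 0.08. Of 23 neural progenitor genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.18, camera adjusted p = 0.00319), with gfap at -0.54 ± 0.09, sox1a at -0.45 ± 0.10 and the riser pou5f3, a pluripotency factor, at 0.41 ± 0.09. With an estimated correlation the adjusted p of the progenitor list was 0.0953. For both lists that was the highest over the alternatives, which began at 0.000144 for eye and midbrain and 0.00172 for progenitors. Of the other probe sets of sox1a, 1 gave -0.35 and 1 gave -0.09 (adjusted p = 0.553). The eye and midbrain median was -0.0783 without the control array numbered 1 and -0.0607 without the morphant array numbered 2. It was -0.23 among the 60% of probe sets with the highest mean. The sox1a call was lost without the control array numbered 1 (adjusted p = 0.0577) or the morphant array numbered 3 (0.0527). The pou5f3 call was lost without the control array numbered 2 (0.0513) or the morphant array numbered 3 (0.0519).

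Cell cycle genes were lower as a group. Of 31 measured, 15 fell and none rose at 10 somites (23 fell and 1 rose adjusted over the list alone), with a median of -0.31 (camera adjusted p = 3.04e-12, and 0.0281 with an estimated correlation). The cytokinesis kinesin gene kif23 fell by 0.48 ± 0.07 and the replicative helicase genes mcm4 and mcm5 by 0.41 ± 0.06 and 0.39 ± 0.07. A second probe set of kif23 gave -0.16 (adjusted p = 0.399). In the same embryos 5 of 26 genes of the p53 and morpholino response list rose and none fell (6 rose adjusted over the list alone; median 0.14, camera adjusted p = 0.0296, and adjusted p = 0.435 with an estimated correlation). These were the apoptotic caspase gene casp8 at 0.77 ± 0.11, phlda3 at 0.58 ± 0.10, the p53 regulator mdm2 at 0.40 ± 0.09 and, chosen after their values were seen, ccng1 at 0.37 and jun at 0.36. The adjusted p of this list ran from 0.00111 to 0.435 over its alternatives. The call was also lost with array weights (0.136, median 0.0781) and among the 60% of probe sets with the highest mean (0.0576). The median was 0.0848 with the mean of a gene's probe sets. The adjusted p was 0.249 without the control array numbered 3, where the median was 0.0593, and 0.0726 without the morphant array numbered 3. The gene mdm2 lost its call without the morphant array numbered 2 (0.0584) or 3 (0.0678).

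Retinoic acid signalling genes were lower on balance, with 4 of 21 fallen and 2 risen at 10 somites (5 and 2 adjusted over the list alone; median -0.09, camera adjusted p = 0.0279, and adjusted p = 0.105 with an estimated correlation). Besides cyp26b1 these held aldh1a2, the enzyme that makes retinoic acid in the trunk, at -0.55 ± 0.08, and cyp26c1 at -0.98 ± 0.14. The hindbrain segmentation list also holds cyp26b1 and cyp26c1, so the results of both lists are not separate. Over the list's alternatives the adjusted p ran from 0.000453 to 0.105, and it was 0.0602 without the control array numbered 3 and 0.0601 with array weights. The 3 other probe sets of cyp26b1 ran from -2.46 to -0.42, the last not called (adjusted p = 0.0531). Of 14 myogenic regulators 2 fell (3 adjusted over the list alone; median -0.11, camera adjusted p = 0.0489), myog and, at -0.35 ± 0.09, six4a. This call was lost with an estimated correlation (adjusted p = 0.248), with the replicate block (0.0592), without the control array numbered 1 (0.133) or 3 (0.0602) and without the morphant array numbered 3 (0.0726), and its lowest adjusted p over the alternatives was 0.0152. It was also lost with array weights (0.0767), with the mean of a gene's probe sets (0.0603) and without the 4 arrays numbered 1 (0.0926). The median was -0.18 among the 60% of probe sets with the highest mean. The six4a call was lost without the control array numbered 1 (0.0874) or the morphant array numbered 2 (0.0935).

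Of 25 blood genes 2 fell and 1 rose at 10 somites (2 and 1 adjusted over the list alone; median -0.09, camera adjusted p = 0.0421, and between 0.00548 and 0.435 over the alternatives, the last with an estimated correlation). The list's call was lost with array weights (0.0767), with the mean of a gene's probe sets (0.0649) and without the control array (0.166) or the morphant array (0.0726) numbered 3. Its median was -0.14 without the control array numbered 2 and -0.15 without the morphant array numbered 1. Of 18 Fgf signalling genes 2 fell, also adjusted over the list alone, dusp2 at -0.32 ± 0.08 and dusp6 at -0.28 ± 0.07 (median -0.10, camera adjusted p = 0.0489). That adjusted p was 0.435 with an estimated correlation, 0.0708 with the replicate block and between 0.0164 and 0.435 over all alternatives. The call was also lost among the 60% of probe sets with the highest mean (0.0871), without the 4 arrays numbered 1 (0.0926) and without the control array numbered 2 (0.151) or the morphant array numbered 1 (0.107) or 2 (0.104). The dusp2 signals (5.56 and 5.24) lay within the tag range. A second probe set of dusp6 gave -0.10 (adjusted p = 0.424). The dusp2 call was lost without the control array numbered 2 (0.0978) or the morphant array numbered 1 (0.0535), 2 (0.077) or 3 (0.0552). The dusp6 call was lost without the control array numbered 2 (0.0753) or 3 (0.0552) or the morphant array numbered 1 (0.0856) or 2 (0.0796). The median of the Fgf list was -0.17 without the control array numbered 3 and -0.0673 without the morphant array numbered 2. The yolk layer and plasma protein list, at a median of -0.05, was not called (camera adjusted p = 0.0596, and between 0.00113 and 0.179 over its alternatives). It was with the replicate block (0.0487) and without the control array numbered 1 (0.026, median -0.0794) or the morphant array numbered 2 (0.0305).

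At 18 somites egr2b was again the gene with the lowest fold change, at -3.32 ± 0.11 (control 7.81 ± 0.12, morphant 4.49 ± 0.24, SD, n = 3; adjusted p = 7.49e-10). Contractile genes of heart and fast muscle and neural genes were among the others with low values. The heart light chain gene cmlc1 fell by 1.85 ± 0.12, or 3.62-fold (7.14 ± 0.22 to 5.28 ± 0.22, SD, n = 3), the ventricular heavy chain gene myh7 fell by 1.68 ± 0.14 and the fast muscle heavy chain gene myhz1.3 fell by 1.58 ± 0.29. The tag control probe sets read 3.63 to 5.28 on these morphant arrays, where egr2b (4.49) and myh7 (4.68) lay within that range and cmlc1 at its upper end. Background therefore limits the size of these fold changes. The fast muscle light chain gene mylpfa fell by 0.91 ± 0.22 (adjusted p = 0.0161) and myog by 0.70 ± 0.15 (adjusted p = 0.00809), while myod1, the determination factor upstream of myog, rose by 0.33 ± 0.08 (adjusted p = 0.0198). The retinoic acid enzymes cyp26b1 and aldh1a2 were at -1.46 ± 0.08 and -1.17 ± 0.08. In all, 1935 probe sets were called, 1102 higher and 833 lower, of which 37 changed at least 2-fold, 11 higher and 26 lower. The balance depends on the scaling, with 905 higher and 1008 lower after median centring and 1074 and 982 after quantile normalization.

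The other genes with the lowest fold changes at 18 somites were the neural factor bhlhe22 at -1.65 ± 0.16 (4.01 in morphants, within the range of the tag control probe sets), mab21l1 at -1.59 ± 0.15 and en2b, a homeobox gene of the midbrain-hindbrain boundary, at -1.28 ± 0.16. Besides pbx2, the highest were the linker histone gene h1-10 at 1.62 ± 0.13, slc16a3b at 1.27 ± 0.21, the clusterin gene clu at 1.16 ± 0.13, the cytochrome oxidase subunit gene cox6b1 at 1.14 ± 0.22, si:ch73-52f24.4 at 1.13 ± 0.16, hoxd9a at 2.14-fold and atf4a at 1.08 ± 0.10, each with an adjusted p of 0.00451 or less. The control signal of slc16a3b (4.98) lay within the tag range. Among the lowest, 6 probe sets were passed over for lack of a symbol. In the panel, hoxb1a and hoxa2b fell by 0.96 ± 0.11 and 0.81 ± 0.09, and myf5 (0.25 ± 0.11, adjusted p = 0.177) and smyhc1, a slow muscle myosin gene (0.17 ± 0.07, adjusted p = 0.14), were not called. The mylpfa fold change was -0.55 without the morphant array numbered 2, its call was lost without the control array numbered 1 (adjusted p = 0.0679), and the myod1 call without the control array numbered 3 (0.0791) or the morphant array numbered 2 (0.0807). Without the control array numbered 1 the count of called probe sets was 1213, and without the 4 arrays numbered 1 it was 677.

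**Figure D2:**
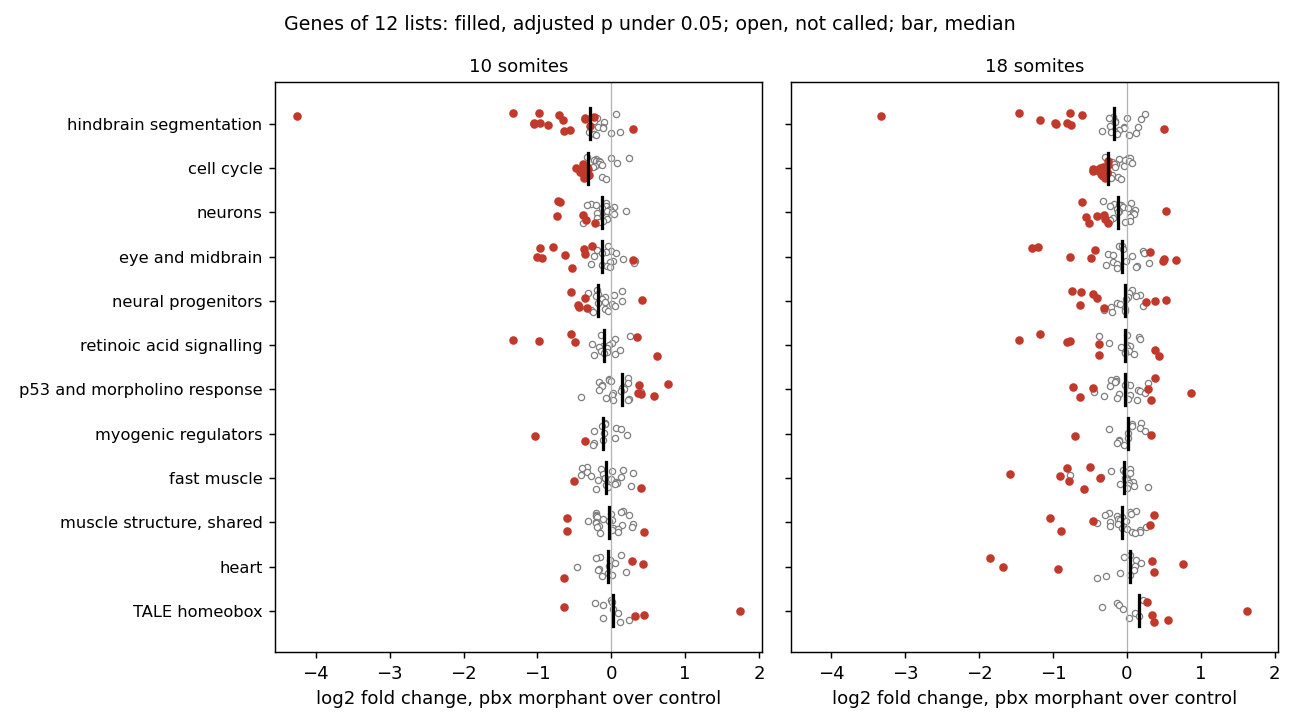
Log2 fold change of morphant over control (horizontal axis) for each measured gene of 12 lists (rows) at 10 somites (left) and 18 somites (right); filled points had an adjusted p under 0.05, open points did not, and black bars are list medians. Cell cycle genes lie close together around medians of -0.31 and -0.25, whereas the fast muscle and heart lists at 18 somites hold a few genes far to the left of a median near 0, which for fast muscle was -0.28 among the 60% of probe sets with the highest mean.

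Of 24 fast muscle genes 7 fell and none rose at 18 somites (8 fell adjusted over the list alone; median -0.04, mean -0.27, camera adjusted p = 0.0183, and adjusted p = 0.557 with an estimated correlation). These included srl, which encodes a calcium binding protein of the sarcoplasmic reticulum, at -0.78 ± 0.09, the tropomyosin gene tpma at -0.58 ± 0.08 and myhz1.3, and, chosen after its value was seen, the calcium pump gene atp2a1 at -0.81. Over the list's alternatives the adjusted p ran from 0.0023 to 0.557, and it was 0.0511 without the control array numbered 1 and 0.115 without the morphant array numbered 2. The median was -0.0148 without that morphant array, -0.12 without the control array numbered 2 and -0.0950 without the morphant array numbered 1. It was -0.28 among the 60% of probe sets with the highest mean. Background can hide a fall of myhz1.3 and atp2a1 at 10 somites. Their control signals there (4.15 and 5.99) were no higher than the highest tag control probe set (6.13). At 10 somites 1 fast muscle gene, srl, fell by 0.50 ± 0.09 and 1, tnnt3b, rose by 0.41 ± 0.09 (2 and 2 adjusted over the list alone; camera adjusted p = 0.393); tnnt3b lost its call without the morphant array numbered 2 (0.0574). Of 27 genes of shared muscle structure 3 fell and 2 rose at 18 somites (3 and 2 adjusted over the list alone; median -0.06, camera adjusted p = 0.391). The muscle acetylcholine receptor gene chrna1 was at -1.04 ± 0.13 and the titin gene ttn.2 at -0.89 ± 0.15, and pdlim5b rose by 0.31 ± 0.07. Of 3 other probe sets of ttn.2, 1 gave -0.91 and the others -0.11 and -0.05. None of the 3 measured slow muscle genes was called at either stage (at 18 somites 2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.679; at 10 somites none, 0.366). Myogenic regulators at 18 somites were 1 higher and 1 lower of 14 (2 and 2 adjusted over the list alone; camera adjusted p = 0.948).

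Beside these muscle values, the 5' control probe set of actin, which the annotation pairs with the muscle actin gene actc1b, was lower in morphants by -0.67 ± 0.10 at 10 somites and -0.80 ± 0.10 at 18 somites. A second 5' probe set was at -0.24 ± 0.10 and -0.45 ± 0.10, the middle probe set at -0.07 ± 0.10 and -0.13 ± 0.10 and the 3' probe set at -0.17 ± 0.13 and -0.19 ± 0.13. The 3' minus 5' difference was 2.60 ± 0.07 in controls and 3.11 ± 0.04 in morphants at 10 somites, and 2.48 ± 0.07 and 3.09 ± 0.14 at 18 somites (SD, n = 3; exact two-sided permutation p = 0.1 at each stage, the smallest that 3 against 3 arrays allow). The same difference for GAPDH changed by 0.02 at 10 somites and 0.21 at 18 somites (exact two-sided permutation p = 0.9 and 0.3).

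Of 16 heart genes 3 fell and 3 rose at 18 somites (5 and 3 adjusted over the list alone; median 0.04, mean -0.20, camera adjusted p = 0.679). Those that fell encode contractile proteins, cmlc1, myh7 and, chosen after its value was seen, myl7 at -0.93. Those that rose are transcription factors, hand2 at 0.77 ± 0.07 (8.31 ± 0.08 to 9.07 ± 0.11, SD, n = 3) and, chosen after their values were seen, gata5 at 0.34 and nkx2.7 at 0.36. At 10 somites hand2 was already higher by 0.42 ± 0.07 and tnnt2a, a heart troponin gene, was at -0.64 ± 0.12 (5.55 in morphants, within the tag range), with 2 heart genes higher and 1 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.715). The remaining riser was gata5 at 0.28 ± 0.08 (adjusted p = 0.0373), whose call was lost without any 1 of the 6 arrays of that stage (adjusted p between 0.0652 and 0.155) and with quantile normalization (0.0554).

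Cell cycle, hindbrain and neuronal lists were called lower at 18 somites too, but not with an estimated correlation (adjusted p = 0.0994, 0.19 and 0.16 with an estimated correlation). Of 31 cell cycle genes 15 fell (16 adjusted over the list alone; median -0.25, camera adjusted p = 7.58e-08), with mcm2 at -0.45 ± 0.06, mcm5 at -0.46 ± 0.07 and mcm4 at -0.40 ± 0.06. Of 28 hindbrain genes 9 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.17, camera adjusted p = 1.56e-06). Of 27 neuronal genes 7 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.12, camera adjusted p = 0.00673), with ascl1b at -0.60 ± 0.08, the synaptic gene snap25a at -0.56 ± 0.07 and the motor neuron factor isl2a at 0.53 ± 0.08. The snap25a signal in morphants (5.10) lay within the tag range. The adjusted p-values with an estimated correlation were the highest over the alternatives of each list, which began at 2.63e-09, 3.33e-07 and 0.000666. Of 21 retinoic acid signalling genes 6 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.02, mean -0.21, camera adjusted p = 0.054, and between 0.000118 and 0.19 over its alternatives), with dhrs3a, a retinaldehyde reductase gene, at -0.82 ± 0.09. The list was called without the control array numbered 2 (adjusted p = 0.0395, median -0.0725) or the morphant array numbered 2 (0.0261, median -0.00117) and among the 60% of probe sets with the highest mean (0.0469). Without the control array numbered 3 its median was 0.0005. Of 13 TALE homeobox genes 5 rose (6 rose and 1 fell adjusted over the list alone; median 0.16, camera adjusted p = 0.0362), among them the targeted pbx2 and pbx4, pknox2 at 0.56 ± 0.10 and meis1b at 0.28 ± 0.06. The list was not tested without the targeted genes, so its call is not separate from their rise. This call was lost with an estimated correlation (adjusted p = 0.233), with the replicate block (0.0935), without the 4 arrays numbered 1 (0.101) and without the control (0.0511) or morphant array (0.0898) numbered 1. The median was 0.25 among the 60% of probe sets with the highest mean. The lowest adjusted p over the alternatives was 0.000411. A second probe set of pknox2 gave 0.12 (adjusted p = 0.483). At 10 somites 3 TALE genes rose and 1, meis3, fell by 0.64 ± 0.11 (3 and 2 adjusted over the list alone; camera adjusted p = 0.268).

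Hox genes changed in both directions. At 10 somites 3 of 42 rose and 9 fell (5 and 10 adjusted over the list alone; median -0.02, camera adjusted p = 0.294), and at 18 somites 14 rose and 11 fell (18 and 13 adjusted over the list alone; median 0.08, mean 0.03, camera adjusted p = 0.673). Split by paralog group, a grouping chosen after the values were seen, 8 of 13 genes of groups 1 to 4 fell at 10 somites and 7 at 18 somites, and none rose. Of 17 genes of groups 9 to 13, 3 rose at 10 somites and 10 at 18 somites, and none fell. Of 12 genes of groups 5 to 8, 1 fell and none rose at 10 somites, and 4 rose and 4 fell at 18 somites. The lowest were hoxa3a, hoxb1a and hoxa2b, and hoxd9a was the highest, at 0.74 ± 0.08 at 10 somites and 2.14-fold higher at 18 somites.

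**Figure D3:**
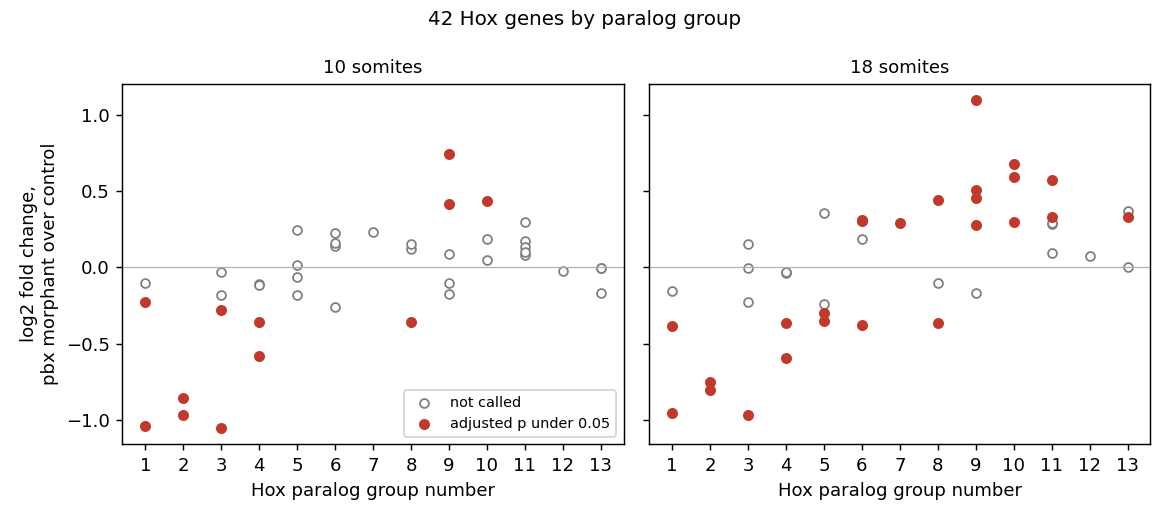
Log2 fold change of morphant over control (vertical axis) of 42 Hox genes against their paralog group number (horizontal axis) at 10 somites (left) and 18 somites (right); filled points had an adjusted p under 0.05. Called genes of groups 1 to 4 lie below 0 and called genes of groups 9 to 13 lie above 0 at both stages.

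Averaged over the stages, with 6 arrays of each treatment, 3321 probe sets were called, 1894 higher and 1427 lower in morphants, or 1662 and 1648 after median centring. The lowest named genes were egr2b at -3.79 ± 0.08 (adjusted p = 9.77e-13), lcp1 at -1.90 ± 0.12, cyp26b1 at -1.40 ± 0.06, bhlhe22 at -1.38 ± 0.11 and pnhd at -1.34 ± 0.12. The highest were pbx2 at 1.69 ± 0.08, slc16a3b at 1.47 ± 0.15, atf4a at 1.23 ± 0.07, h1-10 at 1.19 ± 0.09 and sox32 at 0.97 ± 0.08. Signals of egr2b, lcp1 and bhlhe22 in morphants and of slc16a3b and sox32 in controls lay within the tag range at 1 or both stages, which limits these sizes. Probe sets without a symbol that stood among these numbered 4 on the low side and 2 on the high side.

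The effects at both stages went together. Across 8793 genes, which are not independent replicates, the fold changes at 10 and 18 somites correlated with a Pearson r of 0.685 and a Spearman rho of 0.617. Of 438 genes called higher at 10 somites and 728 at 18 somites 238 were shared, where independent lists of these sizes would share 36.3, and of 398 and 570 called lower 227 were shared, against 25.8. Only 3 genes were called in opposite directions. Among the genes called at 10 somites, 414 of the 438 higher ones and 372 of the 398 lower ones had the same sign at 18 somites.

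**Figure D4:**
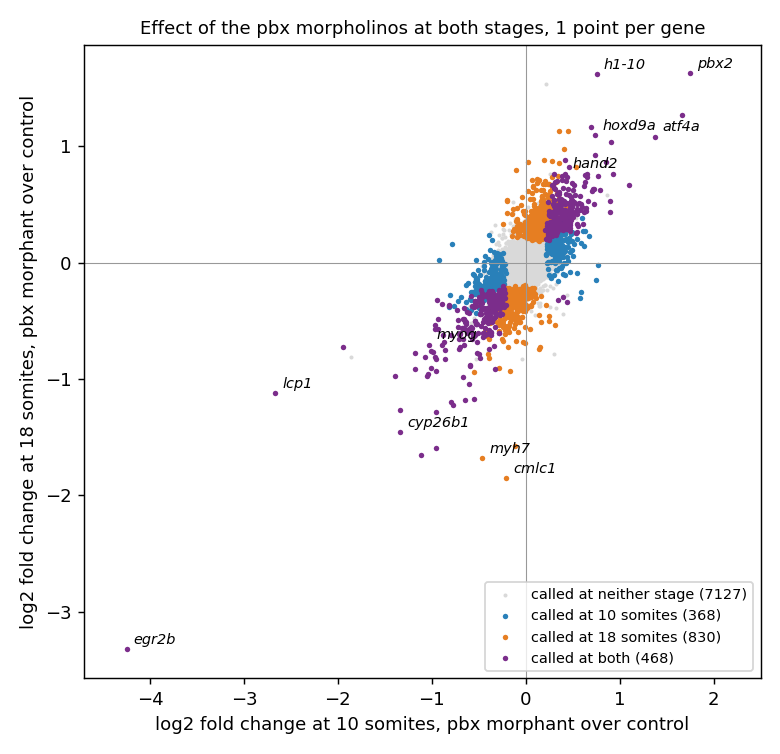
Log2 fold change of morphant over control at 18 somites (vertical axis) against that at 10 somites (horizontal axis), 1 point per gene for 8793 genes, coloured by the stage at which it was called. Most called genes lie along the diagonal, with egr2b at the lower left and pbx2 at the upper right, while cmlc1 and myh7 lie below the diagonal.

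A direct test of the difference between the stages' effects called 5 probe sets, 4 with a lower and 1 with a higher effect at 18 somites, and 1257 had an unadjusted p under 0.05. The heart light chain gene cmlc1 differed most, by -1.64 ± 0.16 (adjusted p = 0.00136), from -0.21 ± 0.12 at 10 somites to -1.85 ± 0.12 at 18 somites. At 10 somites its signals of 5.15 and 4.94 lay within the range of the tag control probe sets (4.18 to 6.13 on control arrays), where background can hide a fall or make it smaller. The difference is therefore not shown to be a change in the effect. For crip2 the effect went from 0.59 ± 0.09 to -0.25 ± 0.09 (difference -0.84 ± 0.13, adjusted p = 0.033) and for the Wnt pathway activator gene rspo1 from 0.44 ± 0.08 to -0.34 ± 0.08 (difference -0.78 ± 0.11, adjusted p = 0.0204), with signals in that range in all 4 groups. For zgc:92606 it went from -0.10 ± 0.09 to 0.80 ± 0.09 (difference 0.90 ± 0.13, adjusted p = 0.0204), and 1 probe set has no symbol. With the replicate block 52 probe sets were called, 33 lower and 19 higher at 18 somites. Genes named elsewhere in the report were among those that only the block called (adjusted p between 0.00341 and 0.0391). Their differences were 1.55 for lcp1, 1.22 for pnhd, 0.95 for szl and alox5b.3, 0.93 for egr2b and 0.87 for h1-10. For myh7, phlda3 and aldh1a2 they were -1.21, -0.88 and -0.63. Signals of lcp1, szl, alox5b.3 and egr2b at 18 somites and of myh7 at 10 somites lay within the tag range in morphants. The count of 5 without the block became 20 without the control array numbered 3 at 10 somites. It became 10 without the control array numbered 1 at 10 somites or the morphant array numbered 2 or 3 at 18 somites. Without the control array numbered 3 at 18 somites it became 2. It was 1 without the control array numbered 2 or the morphant array numbered 2 or 3 at 10 somites, or the control or morphant array numbered 1 at 18 somites, and 0 without the 4 arrays numbered 1.

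From 10 to 18 somites 4 of the 5 highest measured rises in control embryos were those of fast muscle genes. The highest were myhz1.3 at 3.97 ± 0.29, atp2a1 at 3.40 ± 0.19, the myosin light chain genes myl1 and mylpfa at 3.21 ± 0.24 and 2.84 ± 0.22, and fga, a fibrinogen chain gene, at 3.03 ± 0.27. The lowest were szl, a secreted factor of the Bmp pathway, at -4.44 ± 0.12, alox5b.3 at -3.77 ± 0.26, lcp1 at -3.19 ± 0.18, the Wnt receptor gene fzd8b at -2.91 ± 0.11 and si:ch211-152c2.3 at -2.68 ± 0.10; 1 probe set without a symbol stood on each side. At 10 somites the control signals of myhz1.3 (4.15), atp2a1 (5.99) and fga (4.71), and at 18 somites those of szl (3.98), alox5b.3 (3.42) and fzd8b (4.46), were no higher than the highest tag control probe set (6.13 and 5.25), so background limits these sizes and their order. These values carry the offset between the stages' scales, since the median change over all probe sets was -0.78. On the deposited scale 14805 probe sets were called in controls, 255 higher and 14550 lower at 18 somites, and 14773 in morphants, 286 higher and 14487 lower. After median centring of each array the calls were 3786 higher and 4106 lower in controls and 3854 and 4427 in morphants, and after quantile normalization 2989 and 3588 in controls and 3238 and 3797 in morphants. Both raised the median change by 0.77, so the direction of most calls on the deposited scale rests on that offset.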

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

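The tests of a delay with fast muscle genes taken by their rise, of fewer fast muscle cells, of p53 activity in both forms and of cross-hybridization, and leaving out the 4 arrays numbered 1, were chosen only after the result was seen. The values here were singled out because a test of the difference between the stages' effects called them, and each is the effect at 18 somites minus that at 10 somites. Among genes, cmlc1 differed by -1.64 (adjusted p = 0.00136), crip2 by -0.84 (adjusted p = 0.033), rspo1 by -0.78 (adjusted p = 0.0204) and zgc:92606 by 0.90 (adjusted p = 0.0204). A probe set with no symbol differed by -1.03 (adjusted p = 0.0204). The cmlc1 signals at 10 somites (5.15 and 4.94) and those of rspo1 in all 4 groups lay within the range of control probe sets for tag sequences that embryos do not carry, so background limits what these differences show.

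Of 100 drawn splits of the arrays within the stages, 12 gave at least as many calls as the 5 of the real grouping, the real one included, with up to 68 in another. Of the other splits that did so, 10 kept the real grouping of 1 stage, as 20 of the drawn splits did. Such a split holds the treatment effect of 1 stage only, which itself makes a difference between the stages. Most drawn splits, the one with 68 calls among them, also kept some same-numbered pairs together. These splits therefore cannot decide, and chance is not excluded for that count.

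Of the gene lists, 9 were called for the difference between stages. The median difference was -0.19 for fast muscle (camera adjusted p = 0.00836), -0.11 for the p53 and morpholino response (0.00599), 0.18 for eye and midbrain (0.00446), 0.15 for endoderm and pancreas (0.00599), 0.14 for myogenic regulators (0.0223), 0.13 for blood (0.00664), 0.13 for Fgf signalling (0.0223), 0.10 for hindbrain segmentation (0.00599) and 0.0858 for Hox genes (0.00599). Each had an adjusted p = 0.393 with an estimated correlation, the highest over its alternatives, and none was called by fry, which tests the members against no change and not against other genes, and whose smallest adjusted p among them was 0.135. Without the control array numbered 3 at 10 somites the p53 list gave -0.0152 (adjusted p = 0.0779), and it gave -0.0663 without the morphant array numbered 3 at 10 somites, -0.0448 without the control array numbered 3 at 18 somites and -0.0612 without the morphant array numbered 1 there (adjusted p = 0.0504). With array weights it gave -0.0552 and with the mean of a gene's probe sets -0.0668. Without the morphant array numbered 2 at 18 somites fast muscle gave -0.0781 (adjusted p = 0.162), myogenic regulators 0.23 and hindbrain segmentation 0.15, and the Fgf call was lost (0.131). Hindbrain segmentation gave 0.17 without the morphant array numbered 3 at 10 somites, and at 18 somites endoderm and pancreas gave 0.0852 without the control array numbered 2 and Hox genes 0.13 without the control array numbered 3. Without the morphant array numbered 3 at 18 somites the calls of Hox genes, blood and Fgf signalling were lost (adjusted p = 0.0604 each). Fast muscle lost its call without the control array numbered 1 at 18 somites (0.0544) or the morphant array numbered 1 at 10 somites (0.0679), blood without the control array numbered 3 at 10 somites (0.053), and Fgf signalling without the control array numbered 2 (0.112) or the morphant array numbered 1 (0.0625) or 2 (0.0865) at 10 somites. Myogenic regulators lost theirs without the control array numbered 1 (0.0987) or the morphant array numbered 3 (0.0618) at 10 somites and without the control array numbered 3 (0.0637) or the morphant array numbered 1 (0.0504) at 18 somites, and with array weights (0.0638). Without the 4 arrays numbered 1 the calls of fast muscle (0.0697), myogenic regulators (0.0568) and hindbrain segmentation (0.0674) were lost. Background also limits the fast muscle difference. At 10 somites the control signals of myhz1.3 (4.15) and atp2a1 (5.99) were no higher than the highest tag control probe set (6.13). A fall of these genes at 10 somites can therefore be hidden or made smaller, though srl was called there at -0.50. The list's difference is not shown to be a change in the effect.

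At 18 somites 7 of 24 fast muscle genes fell, with a median of -0.78, while the whole list had a median of -0.04 and an adjusted p = 0.557 with an estimated correlation. A general delay of the morphants stays open: 87 genes outside the muscle and heart lists, matched to the 7 on their rise between the stages in controls, had a median of -0.11 (95% bootstrap interval -0.18 to -0.04), which met the bound set beforehand for excluding a delay, 0.5 times the median of the 7, but that bound was wrong because the 7 were taken for their fall. With the 12 fast muscle genes that rose at least 2-fold in controls, whose median was -0.54, the matched genes' median of -0.19 lay 0.0849 above 0.5 times that value, with an interval that spans 0 (-0.12 to 0.28). The match was incomplete: on the scale used for it, these 12 rose by a median of 2.56 in controls and the 70 matched genes by 1.63. A delay would lower genes that rise less by less, so this comparison cannot decide. A loss of fast muscle cells may also be involved, since the 14 list members with a control signal above the array median had a median of -0.42, with an interval (-0.78 to -0.02) that spans the value that would decide. RNA quality stays open too, since 5' actin probe sets were lower in morphants, by -0.80 and -0.45 at 18 somites, and the middle one differed by -0.13. The annotation pairs that actin control with a muscle gene, so its fall is not independent of the muscle genes. The 3' minus 5' difference of GAPDH changed by 0.21 at 18 somites (exact two-sided permutation p = 0.3).

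Cell cycle genes were lower at both stages (adjusted p = 0.0281 and 0.0994 with an estimated correlation), and the p53 and morpholino response list was higher at 10 somites (adjusted p = 0.435 with an estimated correlation; median 0.14, and 0.0593 without the control array numbered 3). The p53 response as the whole cause stays open. The cell cycle median was -0.25 at 18 somites (95% bootstrap interval -0.29 to -0.16), while the 5 p53 list genes that rose at 10 somites had a mean of 0.49 there and -0.02 at 18 somites (SE 0.03 over arrays and 0.0909 over genes), which met the bound set for excluding it, but the 5 were taken for their rise. Over all 26 members, of which 4 rose and 3 fell at 18 somites, the median there minus 0.5 times that at 10 somites was -0.0887, with an interval that spans 0 (-0.23 to 0.0773). An effect of earlier p53 activity that outlasts it was not tested.

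The pbx2 transcript was higher in morphants by 1.75 at 10 somites. Cross-hybridization from another measured Pbx gene is argued against, since the highest fold change among the 5 probe sets of other Pbx genes was 0.45, that of pbx4. Feedback on the gene and a longer life of a transcript that is not translated were not tested, and stay open.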

How the results depend on the processing

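A shared replicate block and leaving out the 4 arrays numbered 1 were chosen only after the data were seen. At 10 somites the 1267 called probe sets became 2040 with the replicate block, 2155 with a block shared by both stages, 2447 with array weights, 480 at an adjusted p under 0.01, 190 at 1.5-fold or more and 333 without the 4 arrays numbered 1. Leaving out 1 array gave between 643 and 1183. At 18 somites 1935 became 801 at an adjusted p under 0.01, 262 at 1.5-fold or more and 677 without the arrays numbered 1, and between 1213 and 1532 without 1 array. For the averaged effect 3321 became 1756, 181 and 1735 under those changes, and between 2649 and 3275 without 1 array. The 5 calls for the difference between stages became 52 with the block, 55 with the shared block, 3 among the 60% of probe sets with the highest mean, 24 with an intensity trend, 32 with array weights, 14 after median centring, 11 after quantile normalization, 1 at an adjusted p under 0.01, 10 with 1 probe set per gene, 10 without cross-hybridizing probe sets and 0 without the arrays numbered 1, and between 1 and 20 without 1 array. Where fewer probe sets or arrays were tested or the threshold was stricter, a lower count follows from that; for the other changes the cause was not tested.

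The stage effect in controls and morphants had 8942 and 8903 calls with the 60% filter and 8424 and 8368 with 1 probe set per gene, both of which test fewer probe sets. It had 7892 and 8281 after median centring and 6577 and 7035 after quantile normalization, which remove the offset between the stages, and between 14649 and 14727 and between 14585 and 14705 without 1 array. Called lists at 10 somites numbered 10, with 6 under array weights, 3 with an estimated correlation and between 6 and 11 without 1 array. At 18 somites they numbered 5, with 0 with an estimated correlation and between 3 and 6 without 1 array. For the difference between stages they numbered 9, with 14 under the 60% filter and 0 with an estimated correlation or with fry. The correlation of the stages' effects was 0.685, and 0.713 under the 60% filter, 0.782 over called genes and between 0.635 and 0.689 without 1 array; the cause was not tested. No called gene or list reversed, while of 54 list results that were not called 23 had a median that changed sign under an alternative. The 1102 higher and 833 lower calls at 18 somites became 905 and 1008 after median centring, and the balance of the stage effects moved with the offset. Beyond the calls given in the report the replicate block changed no call of a named gene or of a list at either stage. Of 142 calls of named genes 117 held whichever array was left out. Fitting only the arrays compared gives no separate value for the averaged effect and the difference. Signal over background was not used. Of 124 named genes, 19 at 10 somites and 12 at 18 somites had a control signal no higher than the highest tag control probe set. Background there can hide a fall or make it smaller, though some falls were called.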

Other observations

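The test of Hox paralog groups was chosen only after the result was seen. Of 18 endoderm and pancreas genes 3 rose and 1 fell at 18 somites (4 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.139), with sox32 at 1.04 ± 0.11 (control signal 4.87, within the range of the tag control probe sets) and the chemokine receptor gene cxcr4a at 0.74 ± 0.09. At 10 somites 1 rose and 3 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.715), the pancreas factor gene ptf1a at -0.47 ± 0.07 (signals 5.68 and 5.21, within that range). In the yolk layer and plasma protein list 3 of 20 fell at 18 somites (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.214), with rbp4, a retinol carrier gene, at -0.83 ± 0.13. Of 23 notochord genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.214), with the laminin gene lamb1a at 0.48 ± 0.08. Of 25 blood genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.92), with gata2a at 0.70 ± 0.09 and spi1b, a myeloid factor, at 0.49 ± 0.09.

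Other lists had calls in both directions at 18 somites and were not called as groups. Of 26 eye and midbrain genes 4 rose and 5 fell (7 and 8 adjusted over the list alone; camera adjusted p = 0.656), with six3a at 0.67 ± 0.08 and rx1 at -0.76 ± 0.09. Of 23 neural progenitor genes 3 rose and 6 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.226), of 23 neural crest genes 3 and 3 (4 and 3; 0.806), of 27 somite segmentation genes 3 and 1 (7 and 3; 0.386), of 21 epidermis and hatching gland genes 1 and 3 (2 and 4; 0.559), of 14 pronephros genes 1 and 1 (1 and 1; 0.326), of 10 vessel genes 2 and 1 (2 and 1; 0.67), of 15 Hedgehog signalling genes 1 and 2 (1 and 2; 0.806) and of 26 p53 list genes 4 and 3 (6 and 6; 0.806). Of 18 Fgf signalling genes 1 rose (1 adjusted over the list alone; 0.988), and of 67 ribosomal protein genes 1 fell (1 adjusted over the list alone; 0.806), rps27.1 at -0.33 ± 0.06.

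Position along the Hox clusters may order the change. Over 42 Hox genes, which are not independent replicates, the fold change went with the paralog group number at 18 somites with a Spearman rho of 0.67 (permutation p = 2e-05, adjusted p = 4e-05 over the stages and both coefficients) and a Pearson r of 0.66 (permutation p = 1e-05, the smallest that 100000 permutations can give). At 10 somites rho was 0.57 (permutation p = 0.00013) and r was 0.57 (permutation p = 4e-05). Median fold changes at 10 and 18 somites were -0.28 and -0.37 for groups 1 to 4, 0.13 and 0.04 for groups 5 to 8 and 0.08 and 0.33 for groups 9 to 13. Groups 5 to 8 lay above groups 9 to 13 at 10 somites, and at 18 somites 4 of their 12 genes rose and 4 fell, so the order holds at best in part. The pattern was found and tested on the same arrays. Genes of groups 1 to 4 such as hoxa2b, hoxa3a and hoxb1a also stand in the hindbrain segmentation list, which was lower. The correlation cannot tell position along the clusters from a lower signal of hindbrain genes.

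For the pbx effect at each stage and the stage effects the 10 splits of 6 arrays are too few for a share under 0.05. The real counts were 1267, 1935, 14805 and 14773 at 1 of 10 splits each, and the highest in other splits 1 at 10 somites and 0 for the others. For the averaged effect, 1 of 100 drawn splits, the real one, gave 3321 calls, and the highest other gave 249. This argues against chance spread between these arrays. It cannot test a chance difference between injected batches, since the labels do not say that the replicates came from separate clutches or injections. Among the 32 splits that part every same-numbered pair, 1, the real one, gave 3321 calls, and the highest other gave 43. The other drawn splits with more calls than 43 kept some pairs together. They and the split with 43 calls also kept the real grouping of 1 stage, so they held part of the treatment effect.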
